A study of Saccharomyces cerevisiae with 102 samples.

How the data were processed

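Dual-channel Agilent arrays of Saccharomyces cerevisiae (102 samples) were taken as deposited. Per the file headers, the scanner files hold red (Cy5, sample) and green (Cy3, reference) signals in scanner intensity units and a log10 ratio of red over green for each spot, made with Agilent Feature Extraction 9.1.3.1 (42 arrays), 9.5.1.1 (22), 9.5.3.1 (32) and 10.7.3.1 (6 batch arrays). That software had subtracted spatially detrended background and normalized the dyes by linear and lowess fits on rank-consistent features. The deposited value tables hold a log2 ratio of Cy5 over Cy3 per gene or probe. Set against the scanner files, each column was the mean scanner log ratio on a log2 scale, except for 3 arrays: allantoin at 0.12 per h (r 0.666 with its own file) and urea at 0.13 and 0.16 per h, each of which matched the other's file. Steps between the scanner software and the value table, as well as growth, RNA extraction and labelling, are not given in the sources used here.

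Scanner files of 101 arrays were used. The file of the 5 min array of the 80 µM proline pulse was garbled, so its column of the deposited table (log2, 2 decimals) stood in, without a background call. Sample groups came from the sample titles. The sample characteristics named another source for 4 steady-state arrays (proline, glutamine and urea at 0.06 per h and glutamate at 0.068 per h) and for the 0 min array of the 400 µM glutamine pulse, and alternatives without the 4 or with the source of the characteristics were run.

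Mean signals (median signals on the batch arrays) were background corrected with limma's normexp and an offset of 50, and log2 ratios were normalized within each array by loess. Control spots and spots marked as outliers by the scanner software were left out. Spots were averaged to probes and probes to systematic names. Of 6288 names on the arrays 5764 (91.7%) were in the reference annotation, which was used for names alone, and the others were kept. A gene was tested when its signal was well above background in either channel on at least 25% of a comparison's arrays. Arrays held 10263 to 43792 spots, red signal was well above background on 87.4% to 99.9% of spots and green on 85.5% to 100% of them, and median red signals ran from 132 to 4200. The lowest correlation between arrays was -0.317, between the batch array at 5 min and an arginine array. The number of arrays limits the precision, and no counting error applies.

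Models were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a mean-variance trend), and a gene passed with a Benjamini-Hochberg adjusted p under 0.05. The 24 steady-state arrays were fitted with nitrogen source and dilution rate (slope per 0.1 per h), each source set against the mean of the other 5, and with source by rate for the interaction. The 5 minute courses were fitted together with windows: early (5, 10 and 15 min) minus reference (0 min and every time from 240 min on, or 0, 120 and 180 min for the mixed pulse), which used 37 of 56 arrays. The seconds series were fitted as slopes per 60 s, and the batch series as a slope per 5 min and a mean ratio. No condition had replicate cultures, so time points within a window and rates within a source stood in for replicates.

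The 25 gene lists were written before the data were examined, as were the comparisons, the first set of alternatives, and the rule for naming genes. The lists covered NCR permeases, allantoin and urea degradation, degradation of proline, arginine and GABA, GATA factors, ammonium assimilation, SPS-sensor permeases, ribosomal proteins, ribosome biogenesis, Gcn4-type biosynthesis, sulfur assimilation, stress and reserve carbohydrates, autophagy, retrograde response, mitochondrial respiration, glycolysis, hexose transporters, purine and one-carbon metabolism, phosphate starvation, G1/S, G2/M, daughter-specific genes, histones, and a-cell, alpha-cell and sporulation genes. Each list was tested with camera at a preset correlation of 0.01 and with an estimated correlation, and with fry, with adjustment over the 25 lists of a comparison.

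Genes were named by this rule: per comparison the 6 highest and 6 lowest coefficients among passing genes with red signal well above background on every array (3 each for a source, 4 each for differences, interaction, seconds series and batch means), the 3 strongest passing members of each called list, and 14 index genes. The text names part of these genes, and any other gene is marked. The relation of the NCR permease mean with the ribosomal protein mean was tested over 24 arrays with 100000 permutations, within sources where means were removed.

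The alternatives were no background subtraction, the scanner software's processed signals, median centring in place of loess, the deposited value tables, no filter, other windows or a spline of time, time as log2(s + 10), slide or scan as a block, array design as a covariate, 4 rate levels as a factor, and leaving out each array or source in turn. Slide and scan came from the file headers. Groups were permuted into up to 100 other splits. Simulated arrays with the same designs, in which 100 genes were changed by each of 2 sizes, were used to test the models: at the larger size 85% to 100% of changed genes were called, at the smaller 52% to 95%, and 5 to 13 of the 142 to 208 calls per comparison were false. The simulated noise was independent between arrays, without slide, scan or time structure. In the real pulse arrays the estimated within-slide correlation was 0.576, so these rates need not hold for the real calls. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.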

Results

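Transcript levels of budding yeast (Saccharomyces cerevisiae) were measured on 102 dual-channel Agilent arrays. Each array set RNA of 1 sample, labelled with Cy5, against a reference labelled with Cy3, and every value is a log2 ratio of Cy5 over Cy3. The reference of 96 arrays was RNA from an ammonium-limited chemostat at a dilution rate of 0.12 per h, and that of the 6 batch arrays was RNA from a batch culture on proline. A chemostat is a culture in which the inflow of medium sets the growth rate.

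The steady-state series held 24 arrays, 4 dilution rates for each of 6 sole nitrogen sources: allantoin, arginine, glutamate, glutamine, proline and urea. The rates ran from 0.06 to 0.21 per h, with 0.068 per h as the lowest for glutamate and 0.2 per h as the highest for urea. In 5 other series a nitrogen source was added to a chemostat as a pulse. These were 400 µM glutamine (12 arrays to 420 min), 40 µM glutamine (12 arrays to 420 min), 800 µM proline (12 arrays to 420 min), 80 µM proline (11 arrays to 360 min), and 20 µM glutamine with 40 µM proline (9 arrays to 180 min). The labels did not state which nutrient limited the pulsed chemostats. The first minutes after 40 µM glutamine (8 arrays to 368 s) and 80 µM proline (8 arrays to 300 s) had series of their own, and 6 arrays followed 400 µM glutamine in a batch culture for 15 min. Each condition and time was a single array with no separate cultures labelled, so p-values measure only the spread between these samples, and the number of arrays limits the precision. Arrays held 10263 to 43792 spots, with red signal above background on 87.4% to 99.9% of them. Values after ± are standard errors of the fitted coefficient.

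A set of 14 index genes was followed in every comparison. They were GAP1 (YKR039W), MEP2 (YNL142W), DAL5 (YJR152W), DAL80 (YKR034W), PUT1 (YLR142W), PUT4 (YOR348C), CAR1 (YPL111W), DUR1,2 (YBR208C), GDH1 (YOR375C), GLN1 (YPR035W), RPL3 (YOR063W), NSR1 (YGR159C), HSP12 (YFL014W) and CIT2 (YCR005C). Probes were matched by systematic name, and no coordinates were used.

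The steady-state arrays asked how transcripts followed growth rate across the 6 sources. Stress genes had the steepest negative slopes per 0.1 per h: HSP26, a small heat shock protein (-3.18 ± 0.26, adjusted p = 1.92e-09), CTT1, the cytosolic catalase (-3.15 ± 0.31, adjusted p = 1.78e-08), and GRE1 (-3.25 ± 0.30, adjusted p = 9.57e-09). The stress and reserve carbohydrate list had 2 higher and 25 lower of 28 (2 and 25 adjusted over the list alone), median -0.95, camera adjusted p = 1.78e-09 and 0.108 with an estimated correlation. Ribosomal protein genes rose with growth rate, led by RPS8A (1.59 ± 0.21, adjusted p = 1.20e-06), with 129 higher and 1 lower of 137 (129 and 1 adjusted over the list alone), median 0.55, camera adjusted p = 9.16e-27 and 0.108 with an estimated correlation. GAP1, the general amino acid permease (-0.81 ± 0.06, adjusted p = 9.90e-10), and MEP2, an ammonium permease (-0.79 ± 0.08, adjusted p = 1.74e-08), fell with growth rate after loess normalization, but with median centring alone their slopes were 0.13 and 0.13, neither past the threshold. The permeases under nitrogen catabolite repression (NCR), the shut-down of genes for poor nitrogen sources when a good source is present, had 9 of 12 lower (9 adjusted over the list alone), median -0.57, camera adjusted p = 0.00285 and 0.108 with an estimated correlation, and this direction was also lost with median centring (median 0.04). DAL80, a GATA repressor of NCR genes, fell under both normalizations (-0.84 ± 0.08, adjusted p = 7.32e-09).

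Nucleotide synthesis rose with growth rate: IMD4, an IMP dehydrogenase, gained most (1.26 ± 0.08, adjusted p = 1.01e-10). The purine and one-carbon list had 20 of 20 higher (20 adjusted over the list alone), median 0.38, camera adjusted p = 1.76e-06 and 0.108 with an estimated correlation. NOP1, which methylates ribosomal RNA, led the ribosome biogenesis genes (1.06 ± 0.08, adjusted p = 6.78e-10). That list had 49 higher and 3 lower of 87 (49 and 3 adjusted over the list alone), median 0.18, camera adjusted p = 3.17e-06 and 0.411 with an estimated correlation. The autophagy list, led by AMS1 (-1.04 ± 0.07, adjusted p = 1.04e-10) and the vacuolar protease gene PRB1 (-1.04 ± 0.10, adjusted p = 8.76e-09), had 17 of 21 lower (17 adjusted over the list alone), median -0.39, camera adjusted p = 3.42e-06 and 0.0683 with an estimated correlation. GDH1, which makes glutamate from ammonium (0.79 ± 0.11, adjusted p = 2.17e-06), and CAR1, the arginase (0.58 ± 0.08, adjusted p = 2.10e-06), rose, while PUT1, GLN1 and NSR1 were not called. Glycolysis genes such as TDH1 (-0.75 ± 0.07) fell after loess and rose with median centring (0.20), as did the list as a whole, from a median of -0.30 to 0.52 (adjusted p = 0.0105 by camera and 0.399 with an estimated correlation). The mating genes of a cells moved with the ribosomal genes. MFA1 (1.27 ± 0.17, adjusted p = 1.11e-06), which encodes a-factor, and STE2 (1.24 ± 0.13, adjusted p = 4.26e-08) led a list with 7 of 7 higher (7 adjusted over the list alone), median 1.23, camera adjusted p = 9.19e-04 and 0.225 with an estimated correlation.

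Of 5959 genes tested with limma, 1942 rose and 1965 fell with growth rate, and 4075 had an unadjusted p under 0.05. With median centring 2257 rose and 1379 fell. Of the 25 gene lists, 12 were called by camera with a preset correlation and 0 with an estimated one (lowest adjusted p = 0.0683). The smaller calls were the GATA factors (adjusted p = 0.0386 by camera and 0.108 with an estimated correlation), Gcn4-type amino acid biosynthesis (adjusted p = 1.38e-05 by camera and 0.160 with an estimated correlation), G1/S (adjusted p = 0.00939 by camera and 0.399 with an estimated correlation) and histones (adjusted p = 0.0127 by camera and 0.411 with an estimated correlation). DAL80, GAP1, MEP2, RPS8A, IMD4 and HSP26 had the fitted sign in 6 of 6 sources, and GDH1 in 5 of 6.

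**Figure D1:**
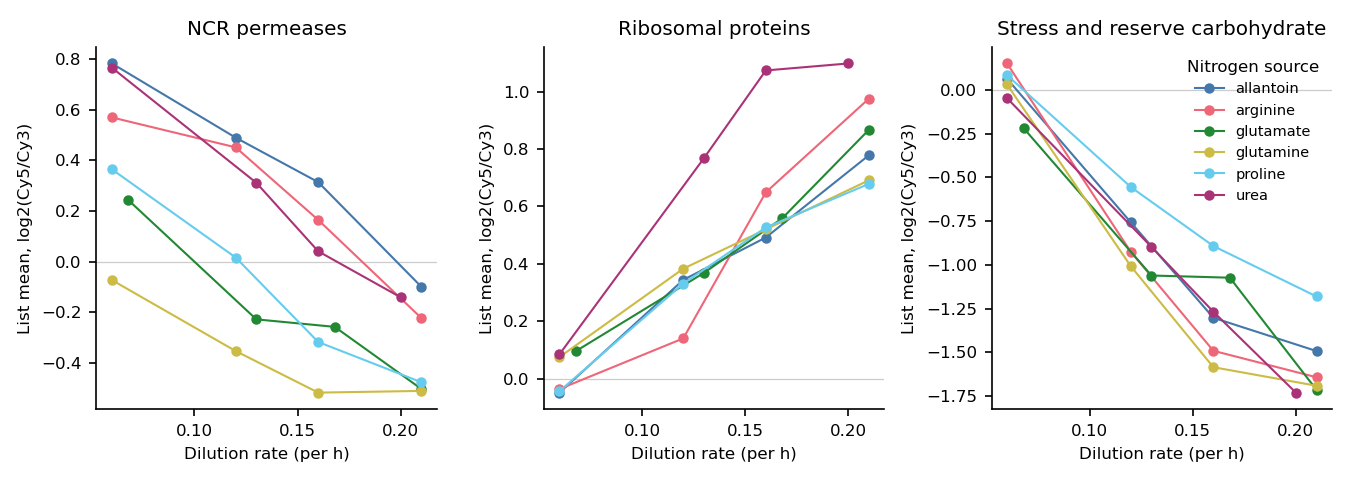
List means of log2(Cy5/Cy3) per array against dilution rate (per h), 1 line per nitrogen source. In allantoin the ribosomal protein mean ran from -0.05 at the lowest rate to 0.78 at the highest and the NCR permease mean from 0.78 to -0.10, a direction that was lost with median centring in place of loess.

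Across the 24 steady-state arrays, the NCR permease mean was set against the ribosomal protein mean, 1 of 8 values computed for this relation. In allantoin the NCR permease mean went from 0.78 at the lowest rate to -0.10 at the highest while the ribosomal protein mean went from -0.05 to 0.78. Glutamine held the lowest NCR permease means, -0.07 and -0.51. Pearson's r was -0.591 (two-sided permutation p = 0.00263, adjusted p = 0.00701) and Spearman's rho -0.580 (permutation p = 0.00377, adjusted p = 0.00754). Without the 2 arrays farthest from the median, allantoin and urea at 0.06 per h, r was -0.486 (permutation p = 0.0232, adjusted p = 0.0371). With each source's mean removed, r was -0.964 (permutation p = 1e-05, the smallest the permutations can give, adjusted p = 4e-05), and within sources of 4 arrays each it ran from -0.951 to -0.992. In every source the NCR permease mean was lower and the ribosomal protein mean higher at the highest rate than at the lowest. Dilution rate was not removed, so these values do not separate a link between the lists from their slopes on growth rate. With median centring the relation over all 24 arrays was absent (r 0.116, permutation p = 0.591, adjusted p = 0.675, rho 0.00957). The relation with source means removed was not run with median centring.

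The source comparison asked which transcripts depended on the nitrogen source at a given growth rate. Genes for the breakdown of arginine and proline were higher in those sources. CAR1 (2.97 ± 0.12, adjusted p = 1.01e-13) and CAR2, ornithine aminotransferase (2.97 ± 0.15, adjusted p = 6.03e-12), were higher in arginine than in the mean of the other 5 sources. The arginine biosynthesis genes ARG3 (-1.94 ± 0.22, adjusted p = 7.89e-06) and ARG5,6 (-1.86 ± 0.09, adjusted p = 5.22e-12) were lower. PUT1 (1.55 ± 0.11, adjusted p = 1.10e-08) and PUT2 (1.55 ± 0.10, adjusted p = 2.21e-09), which oxidize proline to glutamate, the proline permease gene PUT4 (1.59 ± 0.18, adjusted p = 1.91e-05) and GDH2, which releases ammonium from glutamate (1.91 ± 0.14, adjusted p = 1.10e-08), were higher in proline. PUT1 was also higher in arginine (1.20 ± 0.11, adjusted p = 4.17e-07), whose breakdown yields proline.

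The allantoin permease gene DAL4 was higher in allantoin (3.41 ± 0.32, adjusted p = 3.02e-07), urea (3.51 ± 0.32, adjusted p = 1.98e-07) and arginine (2.10 ± 0.32, adjusted p = 4.58e-04). DUR1,2, urea amidolyase, was higher in the same 3 (1.51 ± 0.16, adjusted p = 1.11e-06, 1.65 ± 0.16, adjusted p = 3.47e-07 and 0.69 ± 0.16, adjusted p = 0.00655). The urea permease gene DUR3 was highest in urea (2.44 ± 0.18, adjusted p = 1.87e-08). DAL4 was lower in glutamate (-3.03 ± 0.33, adjusted p = 9.65e-07), glutamine (-3.38 ± 0.32, adjusted p = 2.40e-06) and proline (-2.61 ± 0.32, adjusted p = 5.86e-05). The allantoin and urea degradation list had 7 of 8 higher (8 adjusted over the list alone), median 1.50, camera adjusted p = 6.00e-11 and 0.0966 with an estimated correlation in allantoin. In glutamine it had 6 of 8 lower (6 adjusted over the list alone), median -1.23, camera adjusted p = 7.46e-08 and 0.291 with an estimated correlation. GDH1 was higher in allantoin (1.36 ± 0.16, adjusted p = 3.32e-06) and urea (1.19 ± 0.16, adjusted p = 1.32e-05) and lower in glutamate (-1.74 ± 0.16, adjusted p = 1.06e-07). With the source of the 4 conflicting arrays taken from their characteristics, DAL4 passed in allantoin alone (urea 2.28, arginine 1.58, glutamate -3.21, glutamine -1.64, proline -2.62), and neither DUR1,2 in arginine (0.56) nor GDH2 in proline (1.22) passed. Both arginine calls also ended without the glutamate, glutamine or proline arrays. GAP1 did not pass in the test over all sources (adjusted p = 0.0785).

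**Figure D2:**
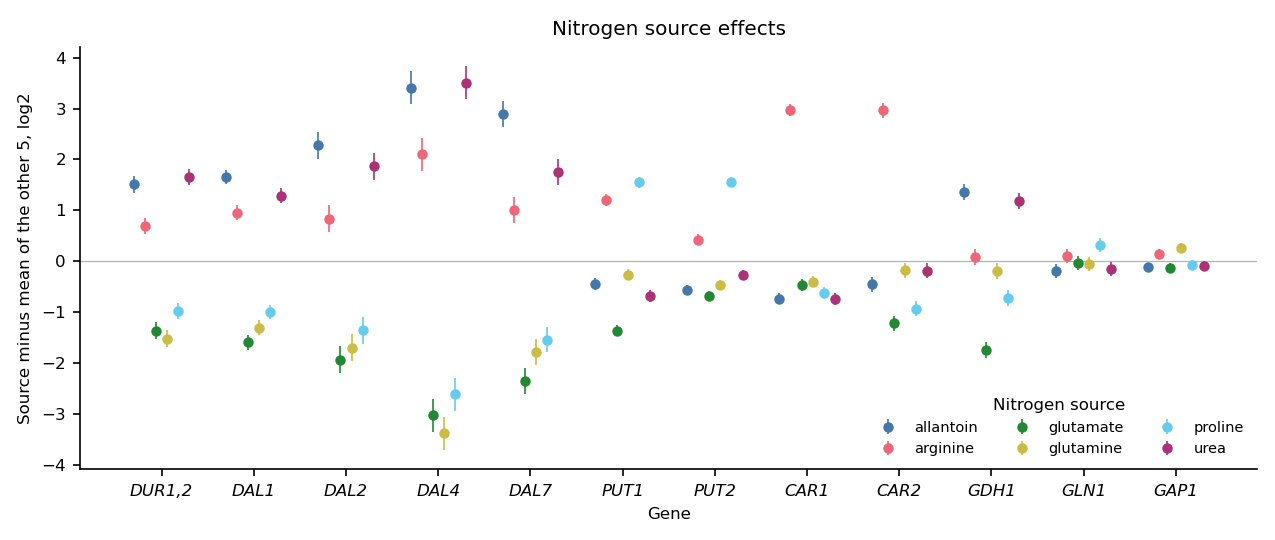
Source effect (log2, that source minus the mean of the other 5, at equal growth rate) of 12 genes, with points for fitted coefficients and bars for standard errors. CAR1 reached 2.97 in arginine and DAL4 3.51 in urea, while GAP1 stayed between -0.13 and 0.27.

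Ribosomal protein genes were higher in urea, with 87 higher and 6 lower of 137 (91 and 7 adjusted over the list alone), median 0.33, camera adjusted p = 1.57e-13 and 0.459 with an estimated correlation. Genes of mitochondrial respiration were lower in glutamine, led by ATP15 (-0.81 ± 0.15, adjusted p = 0.00116), with 11 of 35 lower (19 adjusted over the list alone), median -0.26, camera adjusted p = 3.25e-07 and 0.431 with an estimated correlation. The ATP15 call in glutamine ended with sources from the characteristics (-0.23, adjusted p = 0.654). ATP15 was higher in urea (1.44 ± 0.15, adjusted p = 7.11e-07). The a-cell genes differed between sources too: MFA1 was lower in allantoin (-1.65 ± 0.24, adjusted p = 4.24e-05) and higher in glutamate (1.23 ± 0.24, adjusted p = 0.00109), a call that ended without the allantoin arrays (0.93). Phosphate starvation genes were lower in allantoin (adjusted p = 0.00228 by camera and 0.131 with an estimated correlation). The list of proline, arginine and GABA degradation in arginine had a mean of 0.80 and a median of 0.16, with 4 of 9 higher and 0 lower (4 and 1 adjusted over the list alone, adjusted p = 1.26e-04 by camera and 0.0841 with an estimated correlation).

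With limma, 3403 of 5959 genes differed between sources (3794 at an unadjusted p under 0.05). Against the mean of the other 5, urea had 1144 higher and 942 lower genes, glutamate 707 and 652, allantoin 649 and 577, glutamine 433 and 548, arginine 346 and 383, and proline 114 and 76. With median centring the counts became 278 and 184 for arginine and 252 and 544 for glutamine. Sources from the characteristics gave 859 genes for glutamate, 485 for glutamine and 469 for arginine. Without the 3 mismatching arrays, a fit chosen after seeing the data, urea called 707, allantoin 693 and proline 115. The steady-state arrays of each source shared a scan, apart from the glutamate array at 0.21 per h, and no scan held 2 sources, so source and scan cannot be told apart. Without the glutamine arrays arginine called 1383 genes and proline 719, and leaving out the 0.21 per h array of each brought them to 317 and 49. Without the 0.16 per h array allantoin called 722 genes. Glutamate called 856 without 0.168 per h, and glutamine called 520 without 0.21 per h.

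The interaction asked whether the growth rate slope depended on the source. GDH1 had a lower growth rate slope in glutamate than in the other 5 (slope difference -1.12 ± 0.15, adjusted p = 0.00778), where it stood at -1.05 at the lowest rate and -1.27 at the highest, and VID24, a gene for degrading gluconeogenic enzymes, had the most negative slope in urea (-0.83 ± 0.12, adjusted p = 0.0243). In limma's test over all sources 3 genes passed: VID24 (adjusted p = 0.0332), GDH1 (adjusted p = 0.0447) and RSB1 (adjusted p = 0.0122), the last named after its values were seen because its red signal was not well above background on every array. At an unadjusted p under 0.05 there were 846. Glutamine alone gave more than 1 gene for its slope against the other 5, with 40 higher and 29 lower, among them INO1 (0.88 ± 0.16, adjusted p = 0.0344), ALT1 (0.86 ± 0.16, adjusted p = 0.0344) and RPL34A (-0.69 ± 0.14, adjusted p = 0.0344). Allantoin, arginine and proline gave 0 with limma (271, 409 and 130 at an unadjusted p under 0.05). Leaving out single arrays took the count of 3 from 0, without urea at 0.06 per h, to 7, without arginine at 0.06 per h. Limma called 0 with median centring, with the deposited value table, without the 4 arrays with conflicting labels and, chosen after seeing the data, with the urea labels exchanged (492, 444, 680 and 526 at an unadjusted p under 0.05). It called 4147 with slide as a random block, but that fit estimated a negative within-slide correlation of -0.755. Without the interaction the estimate was -0.010, so counts from this block are not read as evidence of an interaction. The 69 of glutamine went from 0 (limma), without allantoin at 0.16 per h, to 295, without glutamine at 0.12 per h. They also became 0 (limma) with processed signals, with median centring, with the value table and without the 4 arrays with conflicting labels (1158, 929, 944 and 863 at an unadjusted p under 0.05). The same held, in fits chosen after seeing the data, with the urea labels exchanged and without the 3 mismatching arrays (1076 and 1185), while slide as a random block gave 3010. The calls of INO1, ALT1 and RPL34A therefore depended on the processing. Amino acid permeases under the SPS sensor of extracellular amino acids were called here only (0 of 8 higher (3 adjusted over the list alone), median 0.30, camera adjusted p = 0.0114 and 0.155 with an estimated correlation).

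The pulse series asked how an added nitrogen source changed transcripts with time. After 400 µM glutamine GAP1 went from -0.92 at 0 min to -6.35 at 15 min and -3.61 at 420 min, and PUT1 from 0.25 at 0 min to -2.71 at 10 min and -2.83 at 420 min. NSR1, a nucleolar protein for ribosome assembly, went from -1.29 at 0 min to 1.72 at 5 min. The early response was the mean of 5, 10 and 15 min minus the mean of 0 min and every time from 240 min on. Because NCR transcripts were still low from 240 min on, it understated their fall: GAP1 (-1.17 ± 0.72, adjusted p = 0.196) and MEP2 (-1.09 ± 0.84, adjusted p = 0.312) were not called. Both passed against 0 min alone (-3.71, adjusted p = 0.0401, and -4.53, adjusted p = 0.0319). The NCR permease mean was -0.10 at 0 min, -2.46 early, -2.91 at 120 to 240 min and -2.54 at 300 to 420 min.

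Hexose transporter genes rose after 400 µM glutamine, HXT4 (3.33 ± 0.36, adjusted p = 3.11e-08) and HXT1 (3.04 ± 0.36, adjusted p = 1.28e-07) most, with 4 of 7 higher (4 adjusted over the list alone), median 1.67, camera adjusted p = 0.0252 and 0.929 with an estimated correlation. The reference was low here too: the list mean was -0.13 at 0 min, 1.25 at 5 min and -0.75 at 15 min, and between -1.82 and -1.38 from 240 min on. Against 0 min alone 1 of the 7 passed (median 0.61), with HXT4 at 3.08 (adjusted p = 0.132) and HXT1 at 2.42 (adjusted p = 0.0392). Ribosome biogenesis genes rose with them, BFR2 (1.99 ± 0.23, adjusted p = 1.05e-07) first among 77 of 87 higher (82 adjusted over the list alone), median 1.05, camera adjusted p = 1.13e-22 and 0.929 with an estimated correlation. The adenine deaminase gene AAH1 rose (2.19 ± 0.22, adjusted p = 5.20e-09), and NSR1 rose (1.51 ± 0.31, adjusted p = 2.02e-04). The protein kinase gene CMK2 (-2.96 ± 0.37, adjusted p = 2.83e-07), TPO4, a polyamine exporter (-2.53 ± 0.31, adjusted p = 1.66e-07), and ASN1, asparagine synthetase (-1.90 ± 0.33, adjusted p = 2.51e-05), fell, as did CAR1 (-0.97 ± 0.19, adjusted p = 1.15e-04) and GLN1, glutamine synthetase (-0.97 ± 0.32, adjusted p = 0.0157). RTA1 (-3.13 ± 0.56, adjusted p = 4.51e-05) fell against this reference but was higher (0.50) against 0 min alone. The Gcn4-type biosynthesis list was lower (adjusted p = 0.00949 by camera and 0.929 with an estimated correlation) but turned higher with median centring (median 0.20) and had a median of 0.005 against 0 min alone. Stress genes were lower (adjusted p = 0.00200 by camera and 0.929 with an estimated correlation) and histone genes higher (adjusted p = 0.0237 by camera and 0.929 with an estimated correlation). The histone mean was 0.80 at 0 min, 1.44 at 5 min and 0.38 at 15 min, and between -0.16 and 0.09 from 240 min on, and against 0 min alone the list median was 0.09. In all 1304 genes rose and 1293 fell of 5971 (limma, 2997 at an unadjusted p under 0.05). Of the 11 passing genes named for this pulse 5 no longer passed against 0 min alone. RTA1 (0.24), CMK2, TPO4, ASN1 and GLN1 did not pass with slide as a block, nor RTA1 with scan as a block or GLN1 with median centring (-0.23).

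After 40 µM glutamine part of the change was transient. GAP1 went from -0.48 at 0 min to -4.13 at 10 min, -0.53 at 60 min and -0.95 at 420 min. NSR1 rose from -1.30 at 0 min to 1.60 at 5 min and stood at -1.10 at 420 min. Other genes ended away from their 0 min level, on arrays of another slide and scan. PUT4 stood at 0.21 at 0 min and -1.72 at 420 min, and GDH1 at -0.25 and 1.26. NCR permease genes fell, with DAL5 (-3.31 ± 1.06, adjusted p = 0.0272), GAP1 (-2.77 ± 0.72, adjusted p = 0.00691) and MEP2 (-2.56 ± 0.84, adjusted p = 0.0311) in the lead and 7 of 12 lower (9 adjusted over the list alone), median -1.34, camera adjusted p = 3.49e-04 and 0.435 with an estimated correlation. GLN1 (-1.70 ± 0.32, adjusted p = 4.35e-04), GDH1 (-1.66 ± 0.38, adjusted p = 0.00285), PUT1 (-1.81 ± 0.48, adjusted p = 0.00842) and DAL80 (-1.92 ± 0.48, adjusted p = 0.00498) fell too. The ammonium assimilation list was lower (adjusted p = 0.00422 by camera and 0.303 with an estimated correlation). DBP2, an RNA helicase (2.16 ± 0.23, adjusted p = 6.17e-07), and NSR1 (2.11 ± 0.31, adjusted p = 2.75e-05) led the ribosome biogenesis genes, with 82 of 87 higher (83 adjusted over the list alone), median 1.09, camera adjusted p = 8.60e-49 and 0.207 with an estimated correlation. The methionine permease gene MUP1 rose (2.72 ± 0.58, adjusted p = 0.00140), and so did AQR1, an amino acid exporter (2.94 ± 0.46, adjusted p = 5.23e-05). The sulfur list had 14 of 19 higher (16 adjusted over the list alone), median 0.94, camera adjusted p = 4.81e-09 and 0.296 with an estimated correlation. The near-identical asparaginase genes ASP3-1 (-2.68 ± 0.85, adjusted p = 0.0260), ASP3-2 (-2.69), ASP3-3 (-2.69) and ASP3-4 (-2.68) fell together, and their probes need not tell the copies apart.

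With limma 631 genes rose and 517 fell of 5971 after 40 µM glutamine (2031 at an unadjusted p under 0.05), and with median centring 821 rose and 1090 fell. Leaving out the 10 min array left 595 genes, and 73 passed against the single 0 min array, where 13 of the 15 genes named here no longer passed. Most of their log2 changes stayed close (GAP1 -2.91, DAL5 -3.70), but GDH1 went to -0.36. The early and 0 min arrays shared a slide that held no array from 240 min on, and with scan as a block 395 genes passed. That block ended 9 of the 15 named calls, DAL5, GAP1, MEP2, GDH1, MUP1 and the ASP3 genes, slide as a block ended 5, and leaving out single arrays 8.

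After 800 µM proline GAP1 went from 0.07 at 0 min to -4.29 at 15 min, -4.38 at 60 min and -1.56 at 420 min. PUT1 went the other way than after glutamine, from 0.13 at 0 min to 2.42 at 5 min, and was at 1.83 at 420 min. In the early response DAL80 fell (-2.18 ± 0.48, adjusted p = 0.00213), as did DAL3 (-1.66 ± 0.24, adjusted p = 2.48e-05), DAL2 (-1.54 ± 0.19, adjusted p = 3.45e-06) and GDH1 (-1.47 ± 0.38, adjusted p = 0.00810). The allantoin and urea degradation list had 5 of 8 lower (5 adjusted over the list alone), median -1.12, camera adjusted p = 1.70e-04 and 0.377 with an estimated correlation. HXT4 (3.103 ± 0.365, adjusted p = 3.39e-06) and HXT1 (2.26 ± 0.36, adjusted p = 9.68e-05) rose. NOG2 (1.40 ± 0.23, adjusted p = 1.28e-04), a GTPase of the large ribosomal subunit's assembly, led a ribosome biogenesis list with 70 of 87 higher (79 adjusted over the list alone), median 0.84, camera adjusted p = 2.68e-36 and 0.377 with an estimated correlation. The S-phase gene POL30, the DNA polymerase clamp, fell (-1.22 ± 0.21, adjusted p = 1.76e-04), and the G1/S list was lower (adjusted p = 1.70e-04 by camera and 0.662 with an estimated correlation). Daughter-specific genes were higher (adjusted p = 0.00353 by camera and 0.662 with an estimated correlation), though their median turned to -0.11 against 0 min alone. Against 0 min alone several calls named here ended, those of HXT4 and HXT1 among them, but with 1 reference array this need not mean a smaller change. With limma 542 genes rose and 468 fell of 5971 (1773 at an unadjusted p under 0.05), leaving out the 10 min array left 448, and with slide as a block 241 passed, without DAL3, POL30 and GDH1.

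After 80 µM proline PUT1 went from -0.69 at 0 min to 2.89 at 5 min and 0.32 at 360 min. In the early response PUT1 (2.58 ± 0.51, adjusted p = 0.00242) and PUT2 (2.62 ± 0.39, adjusted p = 2.17e-04) rose, with MCH5, a riboflavin transporter (4.005 ± 0.892, adjusted p = 0.00598), and the lysine biosynthesis genes LYS1 (2.63 ± 0.48, adjusted p = 0.00159) and LYS9 (2.29 ± 0.38, adjusted p = 6.94e-04). NSR1 rose (1.47 ± 0.32, adjusted p = 0.00543), and ribosome biogenesis had 63 of 87 higher (78 adjusted over the list alone), median 0.84, camera adjusted p = 3.51e-40 and 0.575 with an estimated correlation. Purine and one-carbon genes were higher (adjusted p = 5.76e-10 by camera and 0.606 with an estimated correlation), as was Gcn4-type biosynthesis (adjusted p = 1.59e-07 by camera and 0.606 with an estimated correlation), while stress genes were lower (adjusted p = 3.45e-04 by camera and 0.606 with an estimated correlation). GAP1 went from -0.40 at 0 min to -1.72 at 15 min, which did not pass (-1.42 ± 0.75, adjusted p = 0.221). With limma 336 genes rose and 297 fell of 5971 (1639 at an unadjusted p under 0.05), and 220 rose and 90 fell in the deposited value table. Single left-out arrays took the count to between 207, without 10 min, and 443, without 0 min. Against the single 0 min array most calls named here ended, but with 1 reference array this need not mean a smaller change. PUT1 stood at -0.69 at 0 min, below its 0.87, 0.46 and 0.32 at 240, 300 and 360 min. NSR1 stood at -1.06, above its -1.53, -1.44 and -1.33 at those times. With scan as a block LYS1 and NSR1 did not pass.

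The pulse of 20 µM glutamine with 40 µM proline joined both patterns. GAP1 went from 0.21 at 0 min to -3.72 at 10 min and -0.06 at 30 min, while PUT1 went from 0.31 to 2.69 at 10 min. In the early response DAL5 (-3.99 ± 1.19, adjusted p = 0.00918), MEP2 (-3.37 ± 0.94, adjusted p = 0.00592), GAP1 (-3.20 ± 0.81, adjusted p = 0.00249), PUT4 (-3.16 ± 0.83, adjusted p = 0.00365) and DAL80 (-2.70 ± 0.53, adjusted p = 2.18e-04) fell. The NCR permeases had 10 of 12 lower (11 adjusted over the list alone), median -1.92, camera adjusted p = 1.76e-04 and 0.398 with an estimated correlation. NSR1 (2.74 ± 0.34, adjusted p = 4.78e-07) and TOD6 (2.74 ± 0.37, adjusted p = 1.26e-06), a repressor of ribosome biogenesis genes, rose. Ribosome biogenesis had 87 of 87 higher (87 adjusted over the list alone), median 1.75, camera adjusted p = 1.90e-53 and 0.238 with an estimated correlation. The ribosomal proteins had 133 of 137 higher (134 adjusted over the list alone), median 1.17, camera adjusted p = 4.03e-33 and 0.368 with an estimated correlation. Stress genes fell, led by GLC3, the glycogen branching enzyme (-2.39 ± 0.55, adjusted p = 0.00117), with 23 of 28 lower (25 adjusted over the list alone), median -1.42, camera adjusted p = 3.89e-08 and 0.398 with an estimated correlation. Glycolysis genes were lower after loess (adjusted p = 2.82e-04 by camera and 0.398 with an estimated correlation), but their median turned from -0.59 to 0.19 with median centring. With limma 976 genes rose and 1127 fell of 5971 (2606 at an unadjusted p under 0.05), and with median centring 1012 rose and 780 fell. With the single 0 min array as reference several of the calls named here ended. The reference levels were close, though. At 0, 120 and 180 min GAP1 stood at 0.21, 0.14 and 0.34 and DAL5 at 0.16, 0.45 and 0.16.

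**Figure D3:**
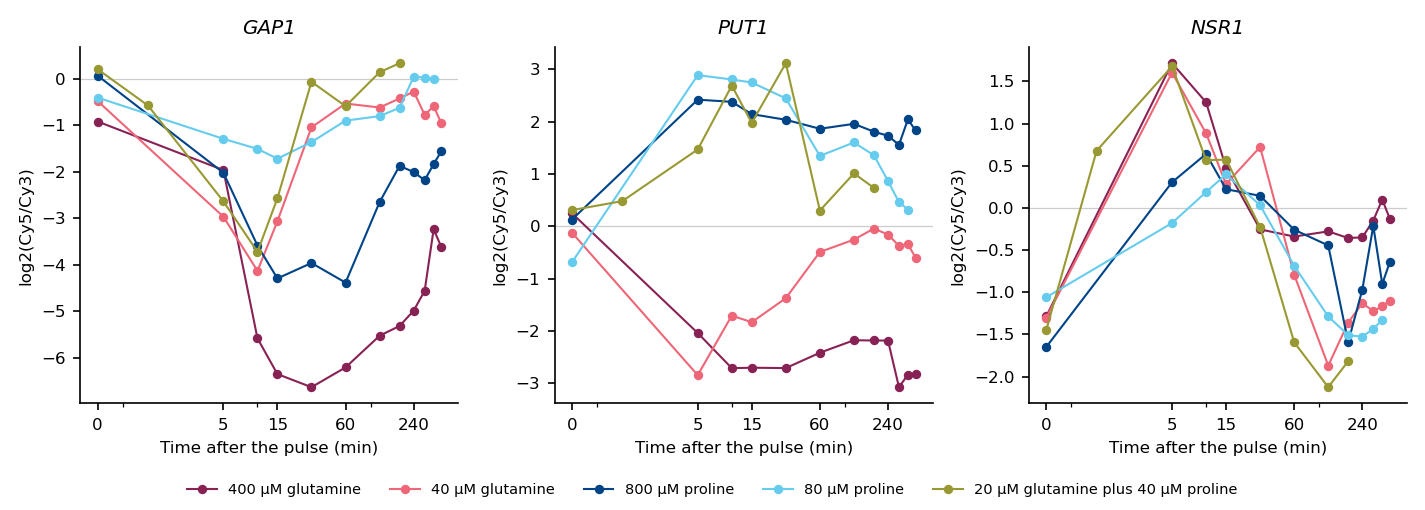
log2(Cy5/Cy3) of GAP1, PUT1 and NSR1 per array against time after the pulse (min, linear to 5 min and logarithmic beyond), 1 line per pulse. PUT1 stood at -2.04 and -2.85 at 5 min after 400 and 40 µM glutamine but at 2.42 and 2.89 after 800 and 80 µM proline.

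The direct tests compared early responses between pulses. PUT1 (-4.39 ± 0.70, adjusted p = 0.00167) and PUT2 (-3.79 ± 0.54, adjusted p = 3.56e-04) were lower after 40 µM glutamine than after 80 µM proline. The list of proline, arginine and GABA degradation was the single list called with an estimated correlation in any comparison (adjusted p = 0.00707). Of its 9 genes PUT1 and PUT2 alone passed, and the arginase gene CAR1 was at -0.25. FMP48, a gene of unknown function named after its values were seen because it fell outside the naming rule, was the other of 3 genes called by limma (log2 1.64, 321 at an unadjusted p under 0.05). PUT2 was higher after the mixed pulse than after 40 µM glutamine (3.02 ± 0.56, adjusted p = 0.0366), as was YPL044C (log2 0.78), also named after its values were seen. Those were the 2 genes of that comparison (956 at an unadjusted p under 0.05). With 0 min alone as reference PUT1 was the only gene left of the first comparison, and limma called 0 genes of the second (11 at an unadjusted p under 0.05). With scan as a block PUT2 passed in neither comparison (-3.87, adjusted p = 0.236, and 2.88, adjusted p = 1.000). Leaving out single arrays took the count of the mixed pulse against 40 µM glutamine from 0, without 5 min of 40 µM glutamine, to 189, without its 0 min. The PUT2 call of that comparison therefore did not hold without this 5 min array.

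The dose comparison of 400 with 40 µM glutamine called 745 higher and 691 lower genes (2249 at an unadjusted p under 0.05), but limma called 0 against 0 min alone, 1 array per course (777 at an unadjusted p under 0.05). HTA1, a histone H2A gene (2.16 ± 0.47, adjusted p = 0.00148), was higher after the larger dose, and the histones had 6 of 8 higher (6 adjusted over the list alone), median 1.22, camera adjusted p = 8.74e-04 and 0.875 with an estimated correlation. From 240 min on the histone mean was -0.16 to 0.09 after 400 µM and 0.88 to 1.18 after 40 µM, and against 0 min alone the list median was 0.29. LYS20 (-1.58 ± 0.35, adjusted p = 0.00157), a lysine biosynthesis gene, was lower, and Gcn4-type biosynthesis had 15 of 37 lower (15 adjusted over the list alone), median -0.74, camera adjusted p = 9.07e-06 and 0.875 with an estimated correlation. From 240 min on that mean was 0.22 to 0.41 after 400 µM and 0.05 to 0.18 after 40 µM, and against 0 min alone the list median was -0.39. NCW2, a cell wall gene (-3.12 ± 0.68, adjusted p = 0.00139), and HAC1, the regulator of the unfolded protein response (-2.91 ± 0.69, adjusted p = 0.00275), were lower. Set against 0 min alone, HTA1 stood at 0.26, LYS20 at -1.73, NCW2 at -0.45 and HAC1 at -0.33. Ribosomal proteins were lower (adjusted p = 0.0379 by camera and 0.916 with an estimated correlation), a direction that turned with median centring (median 0.52) and against 0 min alone (0.07). Median centring moved the median of all genes by 0.143. With slide as a block 123 genes passed and with scan as a block 87, HTA1, LYS20, NCW2 and HAC1 under neither, and leaving out 400 µM glutamine at 0 min raised the 1436 to 2181. GAP1 (1.60 ± 1.02, adjusted p = 0.252) was not called. With median centring GAP1 passed (2.56) and LYS20 did not (-1.08). At 400 µM glutamine against 800 µM proline 390 genes were higher and 468 lower (1717 at an unadjusted p under 0.05), or 577 and 315 with median centring. DAL2 (1.56 ± 0.27, adjusted p = 4.59e-04) and RAD27 (1.08 ± 0.21, adjusted p = 0.00131), a DNA repair nuclease, were higher, and GSC2 (-2.17 ± 0.41, adjusted p = 0.00125), a glucan synthase, was lower. Respiration genes were lower (adjusted p = 1.37e-04 by camera and 0.960 with an estimated correlation) and G2/M genes higher (adjusted p = 0.00446 by camera and 0.960 with an estimated correlation). The reference windows differed here as well: from 240 min on the allantoin and urea degradation mean was -1.27 to -0.83 after 400 µM glutamine and -0.09 to 0.33 after 800 µM proline, and the G2/M mean -0.43 to -0.27 and 0.10 to 0.34. For G2/M genes the median difference was 0.10 against 0 min alone. Against 0 min alone 44 genes passed, and with slide as a block 79, DAL2, RAD27 and GSC2 in neither. The count of 858 ran from 382, without 800 µM proline at 15 min, to 1422, without 400 µM glutamine at 0 min.

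The series sampled in seconds asked how soon the response began. After 40 µM glutamine GAP1 was at 0.50 at 40 s, -0.72 at 120 s and -3.22 at 368 s, and PUT1 had gone from 0.54 at 40 s to -1.77 at 120 s. NSR1 was at -1.29 at 10 s and 0.94 at 120 s. Per 60 s GAP1 (-0.61 ± 0.03, adjusted p = 9.03e-06), MEP2 (-0.57 ± 0.06, adjusted p = 1.31e-04), DAL5 (-0.53 ± 0.04, adjusted p = 2.51e-05) and PUT4 (-0.52 ± 0.04, adjusted p = 4.55e-05) fell, leaving the NCR permeases with 12 of 12 lower (12 adjusted over the list alone), median -0.33, camera adjusted p = 1.43e-08 and 0.0793 with an estimated correlation. MUP1 (0.54 ± 0.09, adjusted p = 0.00204), STR3, a cystathionine lyase (0.53 ± 0.05, adjusted p = 9.35e-05), and MET1, of sulfite reductase's cofactor synthesis (0.45 ± 0.02, adjusted p = 9.03e-06), rose. Sulfur assimilation had 18 of 19 higher (18 adjusted over the list alone), median 0.27, camera adjusted p = 4.06e-13 and 0.0963 with an estimated correlation. Ribosome biogenesis had 87 of 87 higher (87 adjusted over the list alone), median 0.29, camera adjusted p = 2.04e-42 and 0.106 with an estimated correlation. Autophagy had 15 of 21 lower (15 adjusted over the list alone), median -0.12, camera adjusted p = 1.16e-06 and 0.0793 with an estimated correlation. Of 6153 genes 844 rose and 994 fell (limma, 2500 at an unadjusted p under 0.05), and leaving out 120 s raised the count to 2986. With time as log2(s + 10) the call of MUP1 ended (adjusted p = 0.0598).

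After 80 µM proline in seconds, bright red spots were lost on the last 4 arrays, which shared a slide. A spot counted as lost when its log2 ratio was over 4 below the highest spot of its gene on that array. Of spots of genes with a mean red signal over 20000 in the upper rows, 2169 of 2492 (87.0%) in the lower rows were lost, against 0 of 2877 in the upper rows. Because the upper rows chose these genes, that 0 is partly set by the choice. Over all genes the lower rows of the 4 arrays held 464, 393, 569 and 918 lost spots, and the upper rows 1, 0, 0 and 0. Affected genes therefore cannot be read from all spots: GAP1 had a slope of -0.41 ± 0.13 with them (adjusted p = 0.0838) and -0.17 ± 0.02 without them (adjusted p = 0.000686), and NSR1 0.19 ± 0.07 (adjusted p = 0.142) and 0.36 ± 0.03 (adjusted p = 0.000327). The calls of ALD4 (-0.42 ± 0.10, adjusted p = 0.0258), URA5 (-0.35 ± 0.07, adjusted p = 0.0164) and BMH1 (-0.30 ± 0.07, adjusted p = 0.0227) ended without the lost spots (-0.10, 0.07 and -0.04). PUT1 went from 0.72 at 26 s to 2.52 at 112 s on the first slide, before the loss.

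Among genes whose slopes the lost spots did not change, DAL80 fell (-0.37 ± 0.04, adjusted p = 9.79e-04), MCH5 rose (0.55 ± 0.09, adjusted p = 0.00412), and NOG2 (0.30 ± 0.03, adjusted p = 8.36e-04) and UTP9 (0.26 ± 0.01, adjusted p = 2.63e-05), both of ribosome assembly, rose. Ribosome biogenesis with all spots had 80 of 87 higher (84 adjusted over the list alone), median 0.17, camera adjusted p = 3.30e-60 and 0.0700 with an estimated correlation. Without the lost spots 82 of 87 were higher (median 0.17), and with slide as a block as well 15. Early and late times lay on different slides, so time and slide overlap. With limma 369 genes rose and 317 fell of 6016 (1540 at an unadjusted p under 0.05), 248 and 118 with median centring, and 574 and 770 in the deposited value table. With slide as a block 26 genes passed, UTP9 among them (0.26, adjusted p = 0.0213). DAL80 (-0.34, adjusted p = 0.164), MCH5 (0.58, adjusted p = 0.255) and NOG2 (0.33, adjusted p = 0.0896) did not pass, though their slopes stayed about as large. On the first slide alone MCH5 was at -0.023. Leaving out 300 s left 186 genes. With time as log2(s + 10) limma called 0 (1079 at an unadjusted p under 0.05), so all 7 named calls ended, UTP9 included (adjusted p = 0.0546). Leaving out single arrays ended those of ALD4, URA5 and BMH1.

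**Figure D4:**
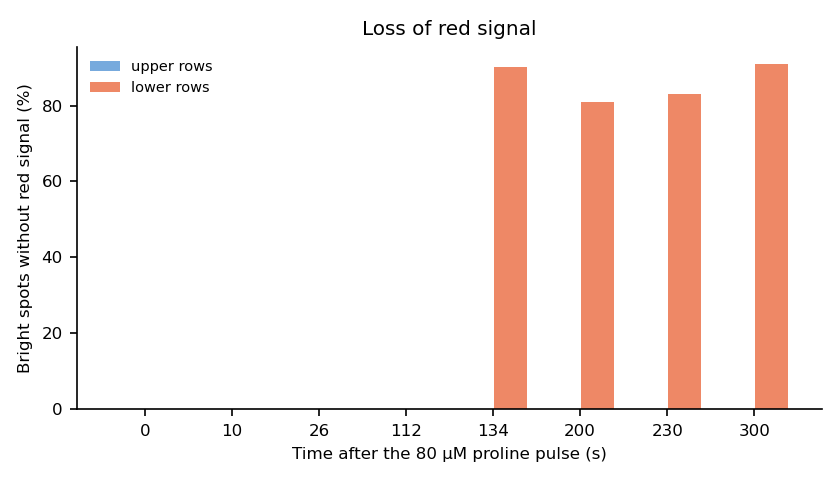
Share of bright spots (%) with lost red signal in the upper and lower rows of each array of the 80 µM proline series, against time after the pulse (s). The lower rows of the 4 arrays from 134 to 300 s lost 2169 of 2492 spots, and the upper rows of these arrays 0 of 2877. Bright genes were chosen by their red signal in the upper rows of the same array.

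The batch arrays asked whether glutamine acted alike in a culture without a chemostat. GAP1 went from 0.43 at 1 min to -4.48 at 10 min, and NSR1 from 0.21 to 2.11. Per 5 min DAL5 (-2.02 ± 0.23, adjusted p = 5.33e-04), MEP2 (-2.00 ± 0.32, adjusted p = 0.00217), GAP1 (-1.91 ± 0.34, adjusted p = 0.00338) and GDH2 (-1.59 ± 0.15, adjusted p = 3.67e-04) fell. Among NCR permeases the series had 11 of 12 lower (11 adjusted over the list alone), median -1.31, camera adjusted p = 1.87e-04 and 0.469 with an estimated correlation. The amino acid permease genes AGP1 (1.65 ± 0.30, adjusted p = 0.00450) and TAT2 (1.36 ± 0.25, adjusted p = 0.00484) rose, but neither passed without the 3 min array (adjusted p = 0.123 and 0.0969). HSP12 (-0.89 ± 0.07, adjusted p = 2.87e-04), PGM2, phosphoglucomutase (-1.09 ± 0.09, adjusted p = 2.94e-04), and HSP26 (-0.97 ± 0.11, adjusted p = 5.03e-04) fell, with 27 of 28 lower (27 adjusted over the list alone), median -0.73, camera adjusted p = 3.98e-10 and 0.409 with an estimated correlation in the stress list. In the mean ratios that follow, the reference was 1 control RNA whose own spread was left out, and a dye bias was not balanced. Their p-values hold neither of these. As a mean over the 6 arrays, RPL31B was higher than the proline reference (1.21 ± 0.10, adjusted p = 2.97e-05), and the ribosomal proteins had 111 higher and 7 lower of 136 (112 and 7 adjusted over the list alone), median 0.46, camera adjusted p = 1.68e-13 and 0.538 with an estimated correlation. Ribosome biogenesis had 87 of 87 higher (87 adjusted over the list alone), median 1.24, camera adjusted p = 5.93e-15 and 0.617 with an estimated correlation. NCR permeases had 12 of 12 lower (12 adjusted over the list alone), median -1.64, camera adjusted p = 0.00114 and 0.538 with an estimated correlation. Of 6169 genes 1487 rose and 1640 fell with time, and 2304 were higher and 2426 lower on average (limma, 3571 and 4825 at an unadjusted p under 0.05).

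**Figure D5:**
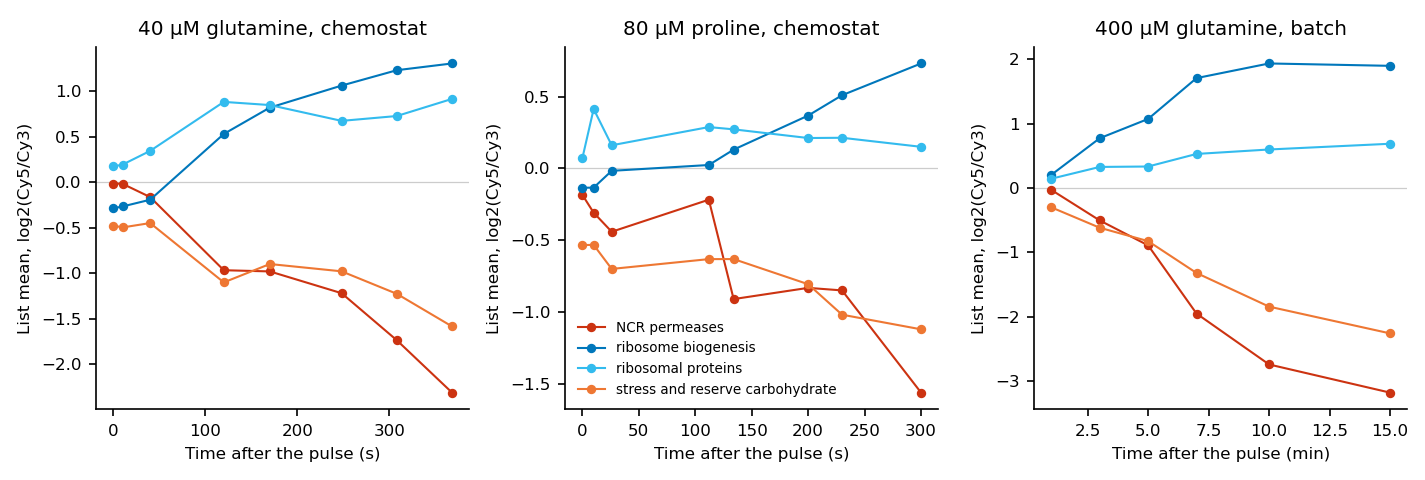
List means of log2(Cy5/Cy3) per array against time (s or min) in the seconds series and the batch series. NCR permease means fell after 40 µM glutamine and in the batch series. After 80 µM proline they ran from -0.44 to -0.18 up to 112 s, and from 134 s on they hold spots with lost red signal.

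Growth rate slopes were set against early pulse responses across 5920 genes, which are not independent replicates. Pearson's r was 0.451 for the mixed pulse, 0.377 for 80 µM proline, 0.155 for 40 µM glutamine, 0.146 for 400 µM glutamine and -0.0518 for 800 µM proline. These values are not like for like, since the mixed pulse had another reference window. After the large pulses some late reference levels had not returned either. NSR1 stood at -1.29 at 0 min and -0.13 at 420 min after 400 µM glutamine, and PUT1 at 0.13 and 1.83 after 800 µM proline. After the mixed pulse 578 genes were higher in both, where 317.5 are given by chance, and 606 lower in both, where 373.7 are. Both counts also exceeded chance after 80 µM proline, with 183 higher in both (109.45 by chance) and 163 lower in both (98.15). They did so by less after 400 µM glutamine, with 466 higher in both (426.3) and 504 lower in both (426.1). The 800 µM proline course lay below chance, with 163 higher in both (177.6 by chance) and 77 lower in both (155.2). After 40 µM glutamine 255 were higher in both (206.8) and 131 lower in both (171.4). Without the ribosomal protein and ribosome biogenesis lists r was 0.413 for the mixed pulse and 0.347 for 80 µM proline. With median centring r was 0.0544 for 40 µM glutamine and 0.251 for 80 µM proline.

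A few lists were called in none of the 20 tests outside the interaction. These were retrograde response and glutamate supply (lowest camera adjusted p = 0.112), the SPS-sensor permeases (0.135), the alpha-cell genes (0.277), and sporulation and filamentous growth (0.347).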

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

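The splits of the samples were planned before their results were seen. The fits against 0 min alone, those with the urea labels exchanged or without the 3 mismatching arrays, the tests of outlier spots and of missing genes per array, and the split of the 300, 360 and 420 min arrays were chosen only after the result was seen. In 6 results here, a test of the difference between groups of samples passed for at least 1 gene, and in 5 a single array lay far from the others of its group.

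Growth rate slopes differed between nitrogen sources for 3 genes, VID24, GDH1 and RSB1, by the interaction term. Among 100 splits 1 was as large, the real one, and the highest other gave 0 genes. These splits exchanged sources within a rate, which put the source differences into the residual. They could therefore hardly call a gene and do not exclude chance. Leaving out single arrays gave 0 to 7 genes. Limma called 0 with median centring, with the value table, without the 4 arrays with conflicting labels and with the urea labels exchanged (492, 444, 680 and 526 at an unadjusted p under 0.05), so these calls depended on the processing and on the labels. With slide as a random block it called 4147, in a fit with a within-slide correlation of -0.755 that is not read as evidence of an interaction. For the slope in glutamine against the other 5 sources 69 genes passed, but 0 with median centring, with the scanner software's processed signals or with the value table, 0 without the 4 arrays with conflicting labels, without the 3 mismatching arrays or with the urea labels exchanged, and 0 to 295 without single arrays. Slide as a random block raised it to 3010 with a within-slide correlation of -0.755. No explanation of this difference was tested, and source cannot be told apart from scan.

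The early response to 400 µM glutamine differed from that to 40 µM for 1436 genes. Splits of the samples exchanged arrays that were ordered in time and tied to slides and scans, so they cannot exclude chance. Drawing 100 gave 1 as large, with 1143 as the highest other. That highest split comes close to the real count. The draws exchanged courses among the early arrays and among the reference arrays separately. A drawn difference can therefore hold level differences between the courses, and what made the highest split was not tested. Slides and scans change with time in both courses, and 123 genes passed with slide as a block and 87 with scan as a block. Against 0 min alone limma called 0 (777 at an unadjusted p under 0.05). Against 800 µM proline 858 genes differed from 400 µM glutamine, and 2 of 100 splits were as large, the highest at 2048 genes. These splits were drawn in the same way and can hold level differences between the courses, so chance is not excluded here. With slide as a block 79 genes passed.

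The early responses to 40 µM glutamine and 80 µM proline differed for 3 genes, PUT1, PUT2 and FMP48. Among 100 splits 7 gave as many, with 118 at the highest, so the count does not exclude chance. These splits, too, can hold level differences between the courses. PUT1 and PUT2 stood apart by -4.39 ± 0.70 and -3.79 ± 0.54 and went in opposite directions in the minute courses, with PUT1 at -2.85 after glutamine and 2.89 after proline at 5 min. For the mixed pulse against 40 µM glutamine 2 genes passed, PUT2 and YPL044C, and 21 of 100 splits gave as many (highest 474), so chance is not excluded there either. With scan as a block PUT2 passed in neither comparison.

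The results within groups were split as well. The early response called 2597 genes after 400 µM glutamine (highest of 55 other splits 1932), 1148 after 40 µM glutamine (478), 1010 after 800 µM proline (437) and 633 after 80 µM proline (20, of 35 splits in all). In each, 1 split was as large, the real one, a share under 0.05. Arrays ordered in time and tied to slides are not interchangeable, so these shares alone do not separate the pulse from that order. The 300, 360 and 420 min arrays, which share a slide and a scan in the 400 µM glutamine and 800 µM proline courses, called 1757, 478 and 437 genes in the courses of 400 µM glutamine, 40 µM glutamine and 800 µM proline when set against the rest. The mixed pulse called 2103 genes and the highest other split 15, but its 10 splits are too few for a share under 0.05. The growth rate slope called 3907 genes (highest of the other splits 1505) and the source effect 3403 (458), each with 1 of 100 as large. The source splits are those of the interaction, which put source differences into the residual. Source was tied to scan, and in most sources the lower rates lay on another slide than the higher ones. These shares alone therefore do not separate source or rate from scan and slide.

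On 4 list means and the share of red spots above background, 0 of 51 tests placed a single array apart from its group, where chance gives about 2.55. On outlier spots and on genes without a value 5 of 18 did, where chance gives about 0.9. For genes without a value both the lowest and the median number per array were 32, and with such ties that expected number does not apply. The batch array at 5 min had 4309 spots marked as outliers by the scanner software against 13 to 23 on the other 5, and 1490 genes without a value against 61 on each. Leaving it out, 2760 genes passed for the batch slope and 4593 for the batch mean. The 248 s array after 40 µM glutamine had 502 genes without a value (next 244), and the glutamine array at 0.16 per h 33 and the glutamate array at 0.21 per h 34, where the other 3 of each source had 32. No explanation of these was tested.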

How the results depend on the processing

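The differences between pulses against 0 min alone, leaving out the lost spots, fitting each slide alone, exchanging 2 urea labels, leaving out the 3 arrays whose value-table columns differ from their scanner files, and median centring of the relations between lists and between slopes were chosen after seeing the data. All others were chosen before. Counts below are of genes past the threshold with limma.

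Apart from single left-out arrays, steady results were the growth rate slope (2622 genes with slide as a block to 4004 with slopes averaged over sources), the source effect (2362 to 3716), the 40 µM glutamine series in seconds (1556 to 1929) and the batch slope and mean (3026 to 3685 and 4651 to 5003). Of 3354 values of 128 named genes, 3158 kept their direction and their side of the threshold, 180 no longer passed, 7 came to pass and 9 reversed. The 3158 include genes that passed in neither fit, whatever their direction. Calls of the interaction and tests without a log2 change, such as the spline, are not among these values. For the results that follow the cause was not tested, except where fewer arrays were fitted.

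Median centring brought arginine to 462 genes, glutamate to 721 and proline to 101, took the interaction to 0 (492 at an unadjusted p under 0.05), raised 40 µM glutamine to 1911 and its difference from 400 µM glutamine to 2540, and brought 80 µM proline in seconds to 366. It moved r of the growth rate slope with the pulse response to 0.0544 for 40 µM glutamine and 0.251 for 80 µM proline. The relation of NCR permease and ribosomal protein means was lost (r 0.116), and slopes changed sign to 0.13 for GAP1 and 0.13 for MEP2, neither past the threshold, and to 0.20 for TDH1. Without background subtraction the mixed pulse differed from 40 µM glutamine at 1 gene and 80 µM proline in seconds called 1168. With processed signals these were 1 and 1305, and 80 µM proline called 313. In the deposited value table they were 1, 1344 and 310, proline called 126, and the interaction called 0 (444 at an unadjusted p under 0.05).

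Among the label choices, leaving out the 4 arrays with conflicting labels gave proline 288 and the interaction 0 (680 at an unadjusted p under 0.05). Sources taken from the characteristics gave arginine 469, glutamate 859, glutamine 485 and the interaction 7. With 4 rate levels proline called 350. Exchanging the urea labels took the interaction to 0 (526 at an unadjusted p under 0.05). Without the 3 mismatching arrays, and so with fewer arrays, allantoin called 693, proline 115, urea 707 and the interaction 1.

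The reference window moved counts in the pulses as well. Against 0 min alone, a single array assumed to vary like the others, 40 µM glutamine called 73, 800 µM proline 226, 80 µM proline 1 and the mixed pulse 622, and RTA1 after 400 µM glutamine reversed to 0.50. The differences against 0 min alone called 0 (glutamine doses, 777 at an unadjusted p under 0.05), 1 (40 µM glutamine from 80 µM proline), 44 (400 µM glutamine from 800 µM proline) and 0 (mixed from 40 µM glutamine, 11 at an unadjusted p under 0.05), with 1 reference array per course. Against late arrays alone 40 µM glutamine called 1872, 800 µM proline 1596 and 80 µM proline 1086. With 30 min in the window 80 µM proline called 976. A spline over all times, which tests any change with time, called 4094 after 400 µM glutamine, 2183 after 40 µM, 3592 after 800 µM proline, 1244 after 80 µM and 658 after the mixed pulse.

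Slide and scan moved counts both ways. With slide as a fixed block 400 µM glutamine called 1428, 800 µM proline 241, 80 µM proline 1115, the difference of the glutamine doses 123, that of 400 µM glutamine from 800 µM proline 79, and 80 µM proline in seconds 26, while RTA1 changed sign to 0.24 without passing. With slide as a random block the interaction called 4147 (estimated within-slide correlation -0.755, so not read as evidence of an interaction), 800 µM proline 451, 80 µM proline 1032, and the differences 322 (glutamine doses), 216 (from 800 µM proline) and 4 (mixed from 40 µM glutamine). With scan as a block 40 µM glutamine called 395, 80 µM proline 344, and the differences 87 (glutamine doses), 1 (40 µM glutamine from 80 µM proline) and 0 (mixed from 40 µM glutamine, 66 at an unadjusted p under 0.05). Array design as a covariate gave 5 for that last difference.

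For 80 µM proline in seconds, time as log2(s + 10) called 0 (1079 at an unadjusted p under 0.05), the first slide alone 0 (410) and the second without lost spots 0 (898), both with fewer arrays. Without lost spots 745 passed, and with slide as a block as well 42. URA5 changed sign, without passing, to 0.070 without lost spots, 0.28 on the second slide and 0.14 with the block, which the lost spots explain by construction. MCH5, without passing, was at -0.023 on the first slide alone. An estimated correlation left 1 list call of the 194 made with a preset one.

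Leaving out single arrays or sources gave ranges of 722 to 1569 genes for allantoin, 317 to 1383 for arginine, 856 to 1766 for glutamate, 520 to 1437 for glutamine, 49 to 719 for proline and 0 to 7 for the interaction. Early responses ran from 595 to 1312 (40 µM glutamine), 448 to 1153 (800 µM proline) and 207 to 443 (80 µM proline). Their differences ran from 978 to 2181 (glutamine doses), 382 to 1422 (400 µM glutamine from 800 µM proline), 2 to 5 (40 µM glutamine from 80 µM proline) and 0 to 189 (mixed from 40 µM glutamine). The series in seconds ran from 1242 to 2986 (40 µM glutamine) and 186 to 993 (80 µM proline).

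No paired analysis was possible because no label pairs arrays between conditions, and slide was fitted as a block instead. Signal over background limits the dimmest genes: without the filter on dim probes every count stayed within 1.5 times its value. Slide and scan as fixed blocks were not run for the source effect and the interaction, nor for the 40 µM glutamine series in seconds and the batch series, which lay on 1 slide each.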

Other observations

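The tests of lost red signal, of the array design of the late 400 µM glutamine arrays, of their level against the other 0 min and the glutamate arrays, and of the return from repression were chosen only after the result was seen, as were leaving out the lost spots and fitting each slide alone. The readings of 2 planned tests, marked below, were settled after their values were seen.

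The red signal of bright genes was lost on the last 4 arrays of the 80 µM proline series in seconds (134 to 300 s), on 465, 393, 569 and 918 spots, against at most 25 on any other array. Loss in the lower rows of 1 slide could produce this: over the 312 genes with copies in the upper rows, the upper-row log2 ratio moved by a median of 0.05 (0.0539 in the table of tests) between the first and last 4 arrays, and spots of dim genes in the lower rows were lost in 170 of 76916 cases (0.221%). A fall of these transcripts is argued against, since 0% of the genes fell by over 1 in the upper rows. What removed the dye is not recorded in the files, and an array-side cause such as quenching or scanning was not tested. Whether the slide change itself makes calls in this series stays open: slopes within the first and second slide had r 0.0437 across genes, which met the prediction for a slide difference, but the 40 µM glutamine series on a single slide gave 0.128 between its own earlier and later arrays. Because that comparison is nearly as low, the test was read, after it was seen, as undecided.

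The NCR permease slope on growth rate was -0.57 after loess and 0.04 with median centring. A loess curve pulled by the ribosomal genes is argued against, since a curve drawn without them moved the NCR slope by 14.4% of the way, to -0.48. A trend of ratio on brightness unrelated to growth rate is not settled. That trend followed dilution rate with sources removed (r 0.513 over 24 arrays, permutation p = 0.0211), which goes against it. The steepest trend, however, was 0.38 for glutamate at 0.21 per h, an array of another scan than the other glutamate arrays. Its red signals reached 379240, against 64373 on those arrays, and the test was not repeated without it. A fall of NCR permeases relative to equally bright genes may be what loess shows, but with median centring their slope lay at percentile 9.46 of 10000 brightness-matched lists, whose median was 0.24 and 5th percentile -0.02. After loess it lay at percentile 0.31 of such lists, whose median was -0.13 and 5th percentile -0.38. The median-centred value met the prediction against this reading, and it was read as undecided after it was seen, because the list's 0.04 lay below the lists' median by less than their spread. The brightness trend with growth rate could itself be biological or of the dyes, and the 2 cannot be told apart here.

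After 400 µM glutamine NCR permeases stayed below their 0 min level to the end. Array design or scan of the late arrays is argued against as the whole cause, since arrays at 120 to 240 min with the design of the 0 min array were already at -2.81 against it, and the glutamate arrays, which share the scans of those arrays, were at -0.50 to 0.24. A mislabelled 0 min array, whose characteristics name glutamate steady state, is argued against as the cause: the highest array from 120 min on, at -2.16, lay 1.59 below the lowest of the 4 other 0 min and the 4 glutamate arrays (difference -1.59), beyond their whole range of 0.82. Its correlation was higher with the other 0 min arrays by 0.0263 (0.732 against 0.706), with overlapping ranges for single arrays. An incomplete return from repression after the larger dose may explain the level, as the mean rose by 0.37 (0.372) from 120 to 240 min to 300 to 420 min, but those windows differ in design and scan, so a return and a batch difference cannot be told apart. After 40 µM glutamine the mean was -0.15 at 0 min, -0.55 at 120 to 240 min and -0.93 to -0.78 at 300 to 420 min.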
